A study of Mus musculus with 2 samples.

How the data were processed

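Whole-genome bisulfite sequencing was carried out on the dentate gyrus, micro-dissected from adult male C57Black6 mice of 8 to 10 weeks. The dentate gyrus is a hippocampal region that holds granule neurons among other cells, so levels are averages over the tissue. Bisulfite treatment converts unmethylated cytosine to uracil, which is read as thymine, while methylated cytosine is still read as cytosine. Per the labels' protocols, 3 µg of genomic DNA was mixed with 0.5% unmethylated lambda phage DNA, sheared to about 300 bp, ligated to indexed adapters, converted and amplified by PCR. There was 1 group of 2 libraries, called replicate 1 and replicate 2 from the labels' numbering. The series' design text calls them biological replicates. Bisulfite reads cannot separate methylcytosine from hydroxymethylcytosine.

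Per the submitters' processing notes, reads were handled with Bismark 0.7.5, and the genome build was mm9. Trimming, removal of PCR duplicates and the removal of unconverted reads are not given in the sources used here. The authors deposited 6 tables, 1 for each library and context (CpG, CHG and CHH, where H is A, C or T). CpH here stands for CHG and CHH together. Each table covers cytosines of 1 strand class, named OT in the tables' names, so the opposite strand was not analysed. The tables have no header. Their deposited values are counts of methylated, unmethylated and total reads per cytosine, and a percent of methylated reads, which the authors computed from those counts. In all tables the methylated and unmethylated counts summed to the total in every row, the percent was recovered from the counts to within 1e-06, and no position was listed more than once. The lowest total was 20 reads in 5 tables and 30 reads in the CHH table of replicate 2, so sites below those depths are not in the comparisons. Positions on chromosome 1 reached 197195359. No mm9 sequence or gene annotation was used here, so sites are given by position only, and the planned comparisons by trinucleotide, gene feature, gene body and promoter were not run. The lambda reads were not analysed here.

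Levels were read-weighted: methylated reads over all reads of the sites in a class. To keep contexts comparable, all 3 contexts of a library were set at the highest of its tables' lowest depths, which was 20 reads in replicate 1 and 30 reads in replicate 2. Mitochondrial cytosines were left out of the levels and used as the non-conversion background, on the assumption that they are little methylated. Leaving them out was decided after the data were seen, and levels with them included are given among the alternatives. Intervals are exact Clopper-Pearson intervals at 95%. They cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Where 2 libraries were averaged, the mean ± SD is given. With 2 libraries in 1 group no permutation test between groups exists.

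A site was called methylated by a one-sided exact binomial test of its methylated reads against the mitochondrial CpH rate of its library, with Benjamini-Hochberg adjustment at 0.01 within library and context. Calls for CpG by the same test, and the CpH share of methylated cytosines, were added after the data were seen. Deep segments are runs of sites with more than 1000 reads, grouped within 10 kb, a description also added then. The libraries were compared at nuclear sites with at least 20 reads in both, by a two-sided Fisher's exact test per site with Benjamini-Hochberg adjustment at 0.05 over all contexts. Such a call compares these libraries, not conditions. CpH levels were related to CpG levels and to CpG density (listed CpG sites as a percent of all listed cytosines) across 10 kb autosomal bins. A bin needed at least 10 CpH sites, and 3 CpG sites for the CpG level or 20 cytosines for the density. These bin minimums were set after the data were seen. Spearman's rho had a two-sided permutation p from 100000 resamples, or from 1000 for the alternatives with the most bins.

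The rule for named regions was fixed before the data were examined. In the absence of an annotation of the build, it took the 5 highest and 5 lowest 1 Mb regions by CHG level in replicate 2 among those with at least 1000 CHG sites, and the depth minimum of 20 used there, as deposited, was chosen after the data were seen. The rule also took the shared sites past the Fisher test, by p, up to 10. Gene lists fixed at the same time were not used, because they need gene positions. Autosomal sites of at most 100 reads, and listed neighbours in place of sequence, were choices made for the additional observations after the data were seen.

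The tests were checked on simulated data before use. With the CHG coverages of replicate 2 at 200000 sites, the binomial test called 57.3% of sites with a true level of 10%, 95.6% at 20% and 100% at 40%, and 0.59% of its calls fell on unmethylated sites. With the coverages of the 33963 shared CHH sites of at most 100 reads, the Fisher test recovered 24.5% of sites that gained 20 percentage points and 97% of those that gained 50. Simulated reads were independent draws, with 1 background rate for all sites. The share of false calls in real PCR reads, or where background differs between sites, is therefore not covered. Alternatives were a depth minimum of 20 or 40 reads, a maximum of 100 reads, the mean of site levels, autosomes only, other background rates and thresholds, other bin sizes and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.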

Results

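The series addressed where methylation outside CpG dinucleotides lies in the adult mouse brain. Bisulfite reads of 2 dentate gyrus libraries were available as counts per cytosine. Replicate 1 listed 172020 cytosines with 30594981 read calls, and replicate 2 listed 27435342 cytosines with 791200717 read calls. Replicate 2 held 2881459 CpG, 18322704 CHG and 6231179 CHH sites, against 7959, 39325 and 124736 in replicate 1. The median depth was 23 to 24 reads per listed site in 5 of the tables and 32 reads for CHH in replicate 2, where the depth minimum was 30. Depth was uneven. In replicate 1, nuclear sites with more than 100 reads carried 94.6% of CpG, 76.7% of CHG and 78.3% of CHH read calls, while in replicate 2 they carried 9.40%, 2.02% and 13.5%.

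Much of the depth of replicate 1 came from short segments that were also deep in replicate 2. A segment of chromosome 2 (98502393 to 98507490, mm9) held 46.6% of nuclear read calls in replicate 1 and 2.54% in replicate 2. Up to 289199 and 471268 reads fell on one listed position there. Whether the reads of such deep segments come from 1 genomic position each was not tested, so their levels need not be those of single cytosines. Segments at the start of chromosome 9 (3000085 to 3035215) and further along it (35112834 to 35113166) held 15.9% and 6.59% of the calls in replicate 1. A segment of chromosome 12 (3109880 to 3110106) held 2.87%. CpG methylation in the chromosome 2 segment was 85.6% in replicate 1 and 85.4% in replicate 2. In the chromosome 12 segment it was 90.2% and 90.5%, and there the CHH level was 9.88% and 9.73%. A segment of chromosome 1 (24619508 to 24620050 in replicate 1) had a CpG level of 0.44% in replicate 1 and, over its slightly longer extent in replicate 2, 0.57%. Its CHG and CHH levels were 0.46% and 0.45% in replicate 1, and 0.37% and 0.36% in replicate 2. These lie near the mitochondrial CpH levels of 0.418% and 0.368%. The segment was kept among the nuclear sites, and whether its reads are nuclear was not tested.

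The first comparison set methylation in the 3 contexts side by side. In nuclear DNA most CpG reads were methylated, whereas under 2% of CHG and CHH reads were. The CpG level was 82.8% in replicate 1 and 80.4% in replicate 2, a mean of 81.6% ± 1.71 (SD, n = 2). The CHG level was 0.90% and 0.77%, a mean of 0.84% ± 0.096 (SD, n = 2). The CHH level was 1.68% and 0.93%, a mean of 1.30% ± 0.529 (SD, n = 2). In replicate 2 the exact 95% intervals were 80.3% to 80.4% for CpG, 0.766% to 0.770% for CHG and 0.930% to 0.932% for CHH. The CHH level exceeded the CHG level in both libraries, at all sites and at sites of at most 100 reads. Within libraries the difference was 0.775 points in replicate 1 and 0.163 points in replicate 2, and an exact paired permutation test of 2 libraries cannot give a p under 0.5. The deep segments set the CpG value of replicate 1: at sites with at most 100 reads its CpG level was 67.3%, against 79.8% in replicate 2. The CHH level of replicate 1 was also lower at those sites, 1.23% against 0.89% in replicate 2. The CHH mean there was 1.06% ± 0.245 (SD, n = 2).

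Mitochondrial cytosines gave the background of failed conversion. The mitochondrial CpH level was 0.418% (95% interval 0.413% to 0.423%) in replicate 1 and 0.368% (0.365% to 0.370%) in replicate 2. Mitochondrial CpG sites were at 0.321% and 0.340%. Nuclear CHG levels were thus 2.16 times the background in replicate 1 and 2.09 times in replicate 2. Nuclear CHH levels were 4.02 and 2.53 times the background, and 2.95 and 2.41 times at sites of at most 100 reads. Above background, the CHG level was 0.443% ± 0.060 and the CHH level 0.912% ± 0.493 (SD, n = 2). In replicate 2 alone the levels above background were 0.401% for CHG and 0.563% for CHH. The folds and the levels above background take nuclear DNA to have failed conversion at the mitochondrial rate. In replicate 1, autosomal sites of at most 100 reads followed by another listed cytosine were at 0.942% (CHG) and 1.11% (CHH). In replicate 2 such sites were at 0.432% and 0.355%. Failed conversion may thus be part of the excess of replicate 1, which does not by itself repeat that of replicate 2.

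**Figure D1:**
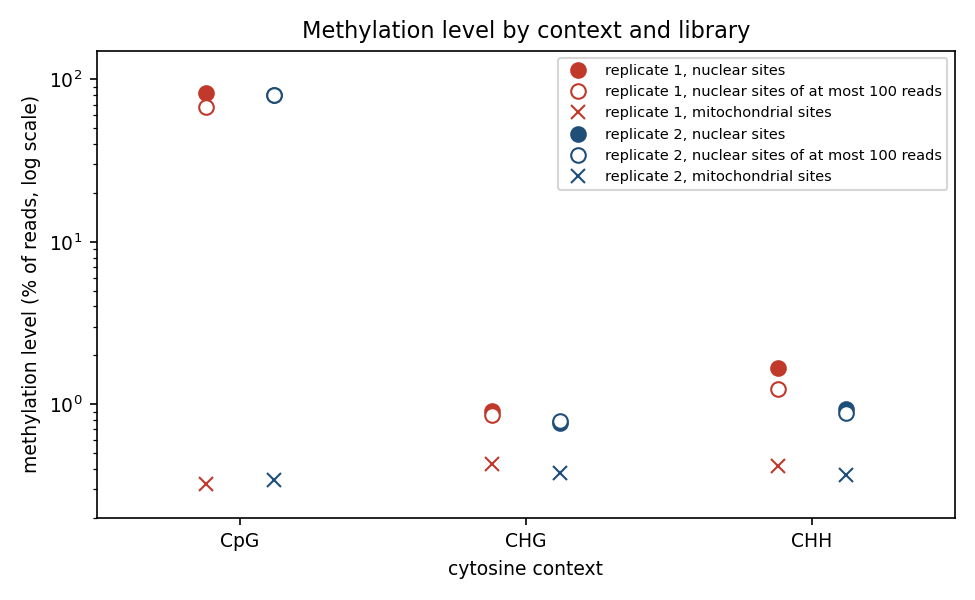
Methylation level (percent of reads, log scale) in CpG, CHG and CHH contexts for each library, at all nuclear sites (filled circles), at nuclear sites of at most 100 reads (open circles) and at mitochondrial sites (crosses). Nuclear CHG and CHH levels lie between 0.77% and 1.68% and mitochondrial levels between 0.321% and 0.428%.

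Single methylated cytosines were then called against that background. In replicate 2, 98.7% of 256072 CpG sites were called methylated, with a median level of 88.2%. CpH sites were called at 205622 of 7993584 positions, or 2.57%. Called CpH sites comprised 34142 CHG sites, 1.93% of those tested, and 171480 CHH sites, 2.75% of those tested. Their methylation was partial, with a median level of 13.3% at CHG and 12.9% at CHH, and at least 3 methylated reads were needed for a call. The CHG median moved with the depth minimum, to 16.7% from 20 reads and 10% from 40 reads. It lay near the lowest level the test can call, so it does not give the typical level of methylated CpH sites. CpH sites made up 44.9% of all cytosines called methylated in replicate 2. In replicate 1, 4760 of 161319 CpH sites (2.95%) and 96.8% of 7738 CpG sites were called. CpH thus made up 38.9% of its cytosines called methylated. The test allows for failed conversion only at the mitochondrial rate, so failed conversion local to some sites would also be called. In replicate 1 this stays a candidate explanation, weighed below, so the 38.9% may include unmethylated cytosines. Most CpH sites had no methylated read: 86.7% of CHG and 86.5% of CHH sites in replicate 2. At depths near the minimum, CpH levels well under 10% at one site were mostly not detectable. The number called in replicate 2 fell to 86614 with the background rate set at 1%, which also took the CpH share of methylated cytosines to 25.6%. With CpG and CHG sites from 20 reads the share was 13.5%, but CHH sites of 20 to 29 reads were not listed, so that share mixes depths.

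The libraries were compared at 5837 CpG, 29243 CHG and 72984 CHH nuclear sites with at least 20 reads in both. Site levels went together for CpG, with a Pearson r of 0.93 across sites, and less so for CHG (0.62) and CHH (0.81), for which most sites were near 0 and Spearman's rho was 0.16 and 0.23. Sites are not independent replicates. Averaged over sites, the CpG level was 65.4% in replicate 1 and 65.1% in replicate 2. Site averages of CHG were 0.85% and 0.73%, and those of CHH were 1.15% and 0.89%, in each case higher in replicate 1. Read-weighted CHH levels were 1.69% and 1.21%. The mitochondrial CHH level of replicate 1 was also higher, by 0.050 percentage points, against 0.479 points at the shared nuclear sites.

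At single sites, 42 CpG, 42 CHG and 248 CHH positions differed between the libraries by Fisher's exact test. The CpG calls went both ways, 16 higher in replicate 1 and 26 higher in replicate 2. Of the CpH calls, 41 of 42 CHG and 238 of 248 CHH sites were higher in replicate 1. The 10 sites with the lowest p all lay in the deep segments. Of these, 7 were on chromosome 2 between positions 98502552 and 98507294, 2 on chromosome 9 and 1 on chromosome 12. The strongest was a CHH cytosine at position 98502552 of chromosome 2, methylated in 4.80% of 15738 reads in replicate 1 and 0.443% of 38573 reads in replicate 2 (Fisher's exact test, adjusted p = 1.87e-241). The CHH cytosine at position 3110040 of chromosome 12 was methylated in 26.0% and 15.7% of reads (Fisher's exact test, adjusted p = 2.95e-70). These p-values take PCR reads as independent and compare these libraries only. They also take all reads listed at a position as reads of 1 cytosine, which was not tested in the deep segments. With at most 100 reads in both libraries 13 sites passed, of which 7 were CpG, 1 CHG and 5 CHH.

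Regions differed widely in CpH methylation. Among 2410 regions of 1 Mb in replicate 2, the CHG level had a median of 0.76% and an SD of 0.18%, which was 8.97 times the SD that counting error gives. CHG and CHH levels, from separate sites, rose and fell together across 2401 autosomal regions (Spearman's rho 0.87). Both contexts were read in the same library, so this correlation does not separate methylation from failed conversion of whole reads. CHG and CpG levels were only loosely related (rho 0.17). Genes in these regions were not identified here.

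By CHG level, the lowest regions were at the background of failed conversion. They were 49000001 to 50000000 of chromosome 7 (0.347%, 95% interval 0.318% to 0.379%), 11000001 to 12000000 of chromosome 7 (0.351%), 19000001 to 20000000 of chromosome 9 (0.376%), 116000001 to 117000000 of chromosome 12 (0.378%) and 22000001 to 23000000 of chromosome 8 (0.378%). Their CHH levels, which did not enter the choice, were between 0.372% and 0.469%. These were low as well, though each lay above the mitochondrial CHH level of 0.366%, by little in the lowest. CpG methylation in the same regions was still 71.2% to 76.5%.

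The highest CHG level, 2.18%, was in 103000001 to 104000000 of chromosome 6. It came from a deep segment at 103599107 to 103599285, and was 0.91% at sites of at most 100 reads. The next highest regions did not contain such sites. They were 136000001 to 137000000 of chromosome 5 (1.72%, 1.65% to 1.80%), 122000001 to 123000000 of chromosome 7 (1.67%), 103000001 to 104000000 of chromosome 7 (1.66%) and 135000001 to 136000000 of chromosome 2 (1.53%). Their CHH levels lay between 1.90% and 2.47%. CpG levels there were between 76.4% and 82.7%. Replicate 1 had too few sites to repeat this comparison.

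**Figure D2:**
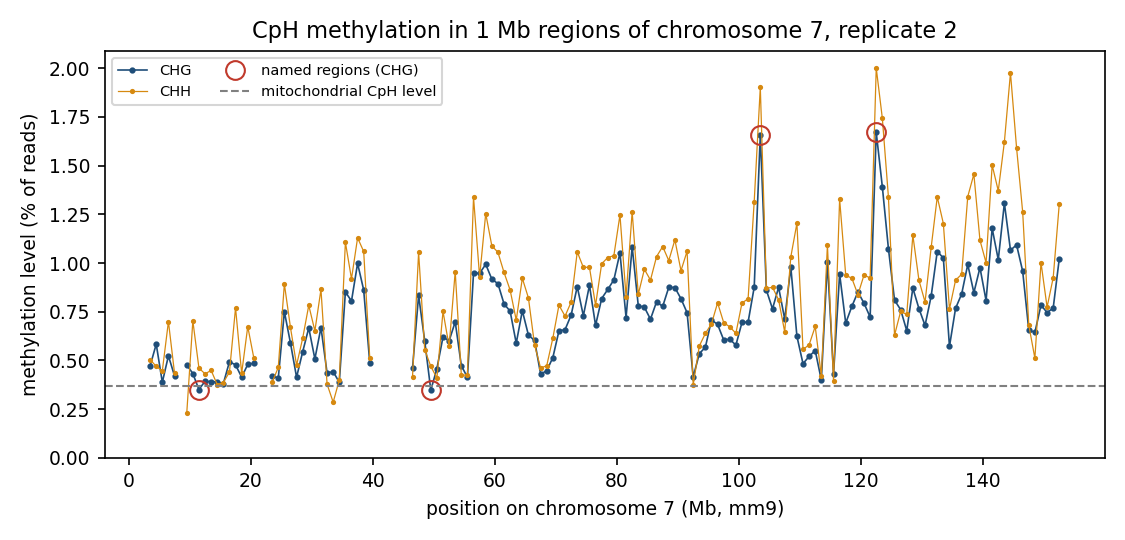
CHG and CHH methylation level (percent of reads) in 1 Mb regions along chromosome 7 (mm9) in replicate 2, with the named regions circled and the mitochondrial CpH level (0.368%) dashed. Gaps are regions with fewer than 1000 CHG sites. The CHG level of the region from 49000001 lies at the dashed line and that of the region from 122000001 at 1.67%.

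CpH methylation was next set against CpG methylation and CpG density in 10 kb bins. In replicate 2 the CpH level rose weakly with the CpG level (rho 0.075 across 29561 bins, permutation p = 1e-05, the smallest that the resamples can give). It also rose weakly with CpG density (rho 0.039 across 147290 bins, permutation p = 1e-05). The relation with density was the stronger one with sites of at least 20 reads (rho 0.091 against 0.035) and in 100 kb bins (rho 0.16 against 0.099). Bins are not independent replicates. Over quintiles of bins by CpG level, the read-weighted CpH level was 0.702% in the lowest quintile, 1.499% in quintile 4 and 0.981% in the highest, with the deep segments included. Over quintiles by density it was 0.864% in the lowest, 0.823% in the middle and 0.968% in the highest. In replicate 1 the rho was 0.16 with the CpG level (284 bins, permutation p = 0.0062) and -0.15 with density (778 bins, permutation p = 4e-05). The density relation was negative in replicate 2 as well at a depth of at least 40 reads (rho -0.066, 3017 bins), and did not pass the test in 1 kb bins (rho 0.0049, permutation p = 0.11). The relation with the CpG level did not pass it at a depth of at least 40 reads (rho 0.056, 763 bins, permutation p = 0.12).

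By chromosome, the X chromosome had lower CpH levels than the autosomes in replicate 2. The CHG level was 0.63% (0.60% to 0.66%) on the X, below each of the 19 autosomes, whose mean was 0.78% ± 0.053 (SD over chromosomes). The CHH level was 0.58% on the X, again below each autosome, whose mean was 0.93%. CpG methylation on the X was 66.0%, below 18 of 19 autosomes. The X is present in 1 copy in males and had 5157 CHG sites at 30 or more reads, against 37868 or more on each autosome. The CpG level of the X minus the autosome mean was -12.2 percentage points, and -2.12 with sites of at least 20 reads. As a mean over sites of at least 20 reads, the CpG level of the X was 78.98%, within the range of the autosomes (77.2% to 79.7%). At 40 reads or more, only 9 of 19 autosomes were above the X for CHG. In replicate 1, with 1013 CHG sites on the X, the X minus the autosome mean was 0.051 points for CHG, and -0.161 at sites of at most 100 reads. It was -0.209 for CHH and -9.13 for CpG, with 7 and 15 of 19 autosomes above the X. At sites of at most 100 reads these were -0.398 and -5.40, with 12 and 17 of 19 autosomes above. The Y chromosome was at 0.45% for CHG and 0.51% for CHH in replicate 2. Among autosomes, chromosome 12 had the highest CHH level, 1.60%, which was 0.90% as a mean over its sites.

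**Figure D3:**
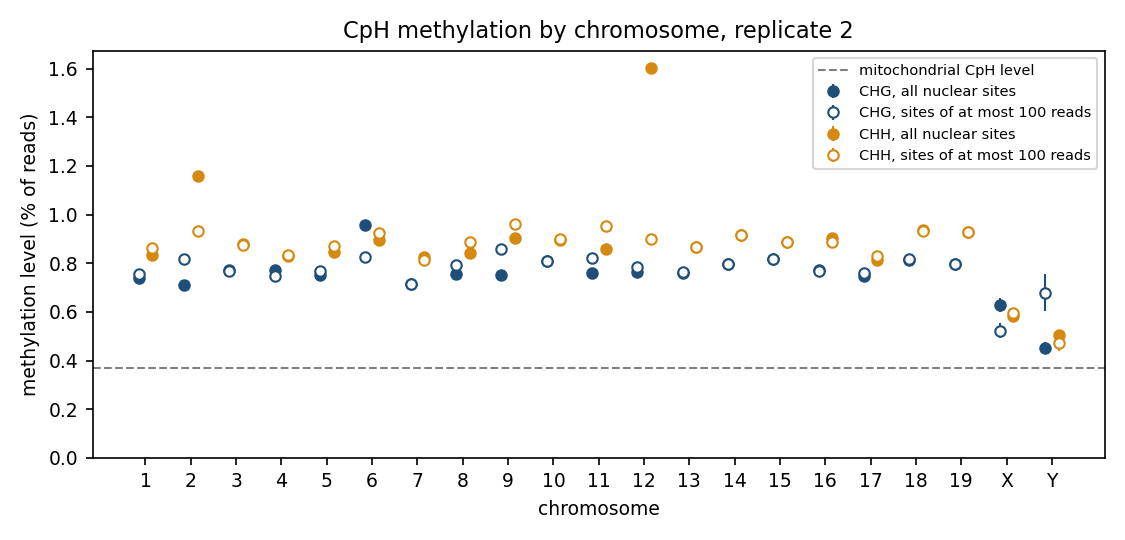
CHG and CHH methylation level (percent of reads) by chromosome in replicate 2, at all nuclear sites of at least 30 reads (filled) and at those of at most 100 reads (open), with exact 95% intervals and the mitochondrial CpH level dashed. The X lies below each autosome in both contexts, and the CHH values of chromosomes 2 and 12 (1.16% and 1.60%) fall to the range of the other autosomes at sites of at most 100 reads.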

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

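Alternatives other than those that include the mitochondria or combine 2 limits were chosen before the data were examined. The CHG mean moved by less than the SD between libraries in each alternative that kept both libraries except background subtraction (0.443%), and the CHH mean in each such one. For CHH that SD was wide (0.529), and the mean was 1.06% ± 0.245 at sites of at most 100 reads. Leaving out a library, which with 2 libraries always moves the mean by less than the SD, gave CpG levels of 80.4% to 82.8%, CHG levels of 0.77% to 0.90% and CHH levels of 0.93% to 1.68%. The CpG mean was 73.5% at sites of at most 100 reads, 74.5% as a mean of site levels, 73.7% with autosomes and at most 100 reads together, and 72.2% with mitochondria included, the last by the unmethylated sites this adds. Depth minimums changed counts by construction. At 40 reads, 35145 nuclear sites and 1671 CpH calls were left in replicate 1, and 643242 sites and 15027 calls in replicate 2. At 20 reads replicate 2 had 27432324 sites and 439790 calls, and CpH made up 13.5% of its methylated cytosines, with no CHH site of 20 to 29 reads to set against CpG. A background rate of 1% gave 86614 calls. Between libraries, CpG differed by 1.79 points (replicate 1 higher) with at least 30 reads, 2.55 with at most 100 and 10.5 with mitochondria, CHH by 0.710 with at most 100 and 0.497 with mitochondria, and at 30 to 100 reads CpG by 0.610, CHG by 0.521 and CHH by 1.22. Sites past the Fisher test numbered 13 with at most 100 reads and 2 at 30 to 100 reads. The X minus the autosome mean in replicate 2 was -2.12 (CpG) and -0.112 (CHG) points at 20 reads, -7.05 (CpG) and -0.476 (CHH) at 40 reads, where 9 of 19 autosomes were above the X for CHG, and -0.265 (CHG) and -0.298 (CHH) with at most 100 reads. In replicate 1 the CHG difference reversed to -0.161 with at most 100 reads, and those of CHH and CpG moved to -0.398 and -5.40. The relation of CpH with CpG level was weaker at 40 reads (rho 0.056, permutation p = 0.12). That with density was reversed at 40 reads (rho -0.066) and weaker in 1 kb bins (rho 0.0049), but higher at 20 reads (rho 0.091) and in 100 kb bins (rho 0.16). The value at 20 reads mixes depths, because CHH sites of 20 to 29 reads were not listed. The cause of these changes was not tested. Of the 10 named regions, 9 remained with at most 100 reads and 0 at 40 reads, where 14 regions had enough sites. No paired analysis was possible because there was no second group to pair with, and contexts were compared within each library. Alternatives for trinucleotides, gene features, gene bodies and promoters were not run, and depth kept low CpH levels at most single sites and most of replicate 1 out of reach.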

Other observations

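The tests of lower conversion throughout library 1 and of a few 1 kb windows were chosen only after the result was seen, as were the ratio rule for levels at background, the background by class of site, the matching of runs on CpG density and the limit of 100 reads. The base after the cytosine went with a large difference in CpH methylation. The mm9 sequence was not used, but a cytosine at the next position shows itself by being listed in the same library. At autosomal sites of at most 100 reads in replicate 2, CHH cytosines followed by a listed cytosine were methylated in 0.355% of reads (1349007 sites), against 0.310% at mitochondrial sites of the same class and 0.368% at all mitochondrial CpH sites. CHH cytosines with no listed cytosine at either of the next 2 positions were at 0.767% (3814341 sites). CHH cytosines with a listed cytosine only at the position 2 on, hence of the CAC or CTC kind apart from neighbours below the depth minimum, were at 2.06% (1002177 sites, 1.79% to 2.25% over the 19 autosomes). CHG cytosines were at 0.432% when followed by a listed cytosine and at 0.795% otherwise. Mitochondrial sites of the same kinds ranged only from 0.297% to 0.436%.

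Both contrasts were set as hypotheses before they were measured. The first was that CpH methylation avoids a following cytosine. Above the pooled mitochondrial CpH level, the CHG level in replicate 2 was 6.60 times higher without one. The CHH level with one lay under that pooled background, which gives no finite ratio. A first computation gave it a negative sign, which by the bound set beforehand counted against the hypothesis, and it was then treated as unlimited. Mitochondrial sites differ in the same direction, with 0.297% at CHG followed by a listed cytosine and 0.396% at other CHG. Against the mitochondrial level of the same class, the CHG ratio was 2.95, between 2.45 and 3.55 over the autosomes, and the CHH ratio 14.1. At sites of at least 36 reads, a limit chosen after the data were seen, they were 1.92 and 9.06, the first under the bound of 2 set beforehand. The second hypothesis was that a cytosine at the position 2 on goes with a higher CHH level. The level above background was 4.24 times higher, between 3.99 and 4.46 times over the 19 autosomes, and 4.19 times against the background of the same class. Replicate 1 did not show the first contrast for CHG, with a ratio of 0.869 against the pooled background, and had 1.32 for CHH. At sites of at least 36 reads these were 1.14 and 1.63, still under the bound of 2. The ratio of replicate 1 for the position 2 on was 2.07, or 1.14 at sites of at least 36 reads. A further hypothesis, also set beforehand, was that methylated CpH sites recur at 8 to 10 bases. The autocorrelation of site levels was 0.091 ± 0.0072 (SD over 19 autosomes) at 8 to 10 bases, 0.067 at 5 to 7 and 0.066 at 11 to 13, and it was highest at 8 to 10 bases in 19 of 19 autosomes. The single highest value among 3 to 20 bases was 0.118 at 8 bases. At 9, 10 and 11 bases the values were 0.0793, 0.0774 and 0.0777, near those at 4 and 5 bases (0.0764 and 0.0767). The value at 2 bases was far higher, 0.335. The autocorrelation was 0.028 at 160 to 200 bases and 0.015 at 80 to 100 bases. Simple sequence repeats may add to these values and were not removed.

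CpH methylation was low inside runs of unmethylated CpG, defined as at least 5 neighbouring listed CpG sites under 10% and at most 300 bases apart. In 2751 such runs the CHG level was 0.355%, at the mitochondrial level, rising to 0.593% within 1 kb, 0.783% between 1 and 2 kb and 0.785% beyond 50 kb. The CHH level was 0.444% (0.409% to 0.480%) inside, above the mitochondrial level, and 0.887% beyond 50 kb. CpG-dense sequence as such is argued against, since 29099 runs of CpG above 80% had a CHG level of 0.886%, 2.497 times higher. Unmethylated runs were denser, with a median of 4.31 against 1.96 listed CpG per 100 bp, and with runs matched on this density the ratio was 2.34, between 1.90 and 3.59 over the autosomes. A lack of CA and CT sites is argued against as the whole cause too, since without a following listed cytosine the level inside was still 0.472 of that beyond 50 kb. These values are from 1 library, and no biological explanation was tested. Runs were chosen by CpG levels of that same library, so the ratios do not separate CpH methylation from failed conversion of whole reads.

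The higher CHH level of replicate 1 at 33963 shared sites of at most 100 reads, a read-weighted difference of 0.710 points and one of 0.351 as a mean over sites, was weighed next. Lower conversion throughout that library is argued against as the whole cause, because the mitochondrial difference was 0.0711 of the read-weighted one, and 0.0508 points as a mean over sites. Failed conversion local to some sites is a candidate explanation: the difference at sites followed by a cytosine, which were at 1.62% in replicate 1 and 0.862% in replicate 2, was 1.11 times that at other sites (bootstrap 95% interval 0.887 to 1.37). Whether a few loci carry the difference stays open: leaving out the 1% of 1 kb windows with the largest excess in each library brought the difference to 0.486 of the whole, but windows chosen by the difference lower it by themselves, so this value, like an earlier form that took windows by the excess of replicate 1 alone, decides nothing. Of 4579 windows, replicate 1 was higher in 1400 and replicate 2 in 1431. The shared sites had a median of 23 reads in replicate 1 and 61 in replicate 2. At low levels the deeper library more often has a methylated read, so these counts do not show how broad the difference is. No biological explanation was tested, and a difference between the animals stays open.

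In replicate 2, 635 windows of 100 bp out of 3325499 with at least 3 sites not followed by a cytosine had a level of at least 20% at those sites. Failed conversion of whole reads may account for part of them: in the 164 windows that also held a site followed by a cytosine, such sites were at 15.2% against 26.4% at the others, a ratio of 0.575 (0.411 to 0.728), and 0.363% in the remaining windows. Only 20.1% of the 164 windows had a level of at least 10% at sites followed by a cytosine, so methylation in the others stays open. In replicate 1, 80 of 14787 windows reached 20%, and in the 50 of them with such sites these were at 31.5% against 30.4% at the others, a ratio of 1.04 (0.866 to 1.199), with 82% of windows at 10% or more. No biological explanation was tested.

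At single sites of at most 100 reads in replicate 2, 104 of 18249464 CHG and 116 of 6165525 CHH cytosines were read as methylated in at least 80% of reads. No sequence was used here, so whether these animals differ from mm9 at those sites, or have another context there, was not checked. None of them was listed in replicate 1. That library listed only 39325 CHG and 124736 CHH sites in all, so this absence does not bear on whether they recur.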
